A study of Rattus norvegicus with 14 samples.

How the data were processed

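The series holds 14 single-channel Affymetrix rat arrays of liver RNA. Per the labels, the total RNA was extracted with a column kit and the hybridisation targets were made by the standard Affymetrix procedure from about 10 µg or about 2 µg of RNA. The authors deposited 1 table with an intensity for each probe set on each array, on a linear scale. The program that computed the intensities, its settings and any normalization are not given in the sources used here. From the values, every array had a trimmed mean, with 2% taken off each end, between 1001.9 and 1002.1, so the deposited intensity of each array had already been scaled to one level. No detection calls were used here. All 14 columns matched a label by title, and 0 columns were left out. No genome coordinates were used.

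The 59 control probe sets were left out, leaving 8740. Each array was scaled to a trimmed mean of 500, and values were taken as log2 of the scaled intensity plus 16, so that an intensity of 0 becomes 4. Differences on this scale understate the change of dim genes. Probe sets whose mean over the 14 arrays lay under the 40th percentile (6.196) were left out, leaving 5244. Gene symbols came from the platform annotation: 7006 probe sets had 1 symbol, 308 had several and 1426 had none listed, which means unnamed here. Of 7018 probe sets with 1 symbol, controls included, 6994 matched a gene of the GRCr8 RefSeq table by Entrez identifier, and 0 symbols changed. The probe set with the highest mean stood for a gene, which gave 3135 tested genes. Of the 90 probe sets called by diet, 77 had 1 symbol, 7 had several and 6 had none listed, and the last 13 are counted but not named, except 3 annotated to both Cyp2c7 and Cyp2c7l1.

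The labels do not say whether the arrays of 1 diet and number at the 2 RNA amounts come from the same liver. For the diet comparison the shift between amounts, the mean over 6 pairs of arrays, was removed from each probe set and arrays of the same diet and number were averaged, giving 4 deficient and 4 sufficient values. These 8 values were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend, and p-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The amount comparison and the interaction of diet and amount used all 14 arrays as separate samples. Whether numbers pair arrays was checked by correlating deviations from the group means. Arrays of 1 diet and number at the 2 amounts correlated at 0.202 to 0.351 in all 6 pairs, against -0.254 to 0.124 for different numbers, and each of the 6 arrays from 2 µg correlated best with the 10 µg array of its own number. The pairing therefore comes from the data and the shared number, not from a statement in the labels, and the values with diet and number as a block are given beside the results they change.

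The 29 gene lists, 20 of pathways and 9 of cell type markers, were written from general knowledge and were tested with camera in limma at a preset correlation of 0.01, on 1 probe set per gene, where at least 5 genes were tested. Camera with an estimated correlation and fry were alternatives. Counts of members that passed are given over all probe sets and adjusted over the list alone.

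The gene lists and a rule for the genes named were fixed before the data were examined. For the diet comparison the rule takes the 12 largest increases and 12 largest decreases among genes that passed with the same sign at both RNA amounts, up to 4 members of each list with the smallest p among those that passed, and, where measured, retinoid genes that include Rbp4, Lrat, Cyp26a1, Rarb, Crabp1, Cyp2c7, Tgm2 and Aldh1a1. For the other comparisons the rule takes up to 5 genes each way. It named 40 genes, of which 38 passed. Members of lists that did not pass or passed only within their list, Fasn, the probe sets called under the block and the genes in the last part of the text were named after their values were seen.

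Alternatives were median scaling, quantile normalization, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, no trend, array weights, each RNA amount alone, 14 separate arrays with amount as a covariate or diet and number as a random block, no removal of the amount shift, the number across diets as a block, and leaving out each animal. Dbp as a covariate was chosen after seeing the data. The fits were tested on simulated arrays in which some of the 5244 tested probe sets were changed by a known amount. For the diet comparison, a change of 0.5 on the log2 scale was recovered for 18.2% of 66 probe sets, a change of 1 for 75% of 60 and a change of 2 for 98.3% of 58, with 8 false among 122 calls. For the amount comparison the shares were 50.8% of 65, 84.1% of 63 and 100% of 59, and with the pairs as a block 48.4% of 62, 89.1% of 64 and 98.2% of 56. For the interaction they were 3.1% of 64, 31.8% of 66 and 81.4% of 59. A list of genes shifted by 0.5 was called and 0 of the other lists were. The simulated genes varied independently of each other, so this says nothing about false calls of lists whose genes are correlated.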

Results

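Liver RNA from 74-day-old male rats was measured on Affymetrix rat arrays after 53 days on a vitamin A-sufficient or a vitamin A-deficient diet. The 14 arrays divided into 7 per diet. In each diet, 4 arrays, numbered 1 to 4, were prepared from about 10 µg of total RNA, and 3 arrays, with the numbers 1, 2 and 4, from about 2 µg. Arrays of the same diet and number were averaged and are called an animal here, so each diet had n = 4. In each diet, animal 3 rests on its 10 µg array alone. The labels describe each liver as that of a rat but do not say which arrays share a liver, so p-values measure the spread between these averaged values. Every array carried 8740 probe sets besides controls. The trimmed mean intensity of an array lay between 1001.9 and 1002.1 and its median intensity between 175.1 and 231. The number of arrays limits the precision of every value. Levels are given as log2 of the scaled intensity plus 16, as mean ± SD over 4 animals, and differences as deficient minus sufficient with their standard error (SE).

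The diet comparison asked which liver transcripts differed after feeding without vitamin A. Of the named genes, Cyp2c7, a cytochrome P450 whose product oxidizes retinoic acid, fell furthest. Its level fell from 12.02 ± 1.24 in sufficient livers to 4.70 ± 0.60 in deficient livers, at a log2 difference of -7.32 (SE 0.52, limma adjusted p = 3.3e-05). The related Cyp2c22 fell by 3.27 on the log2 scale (SE 0.26), which was 9.66-fold, and Cyp2c13, a male-predominant P450, fell by 2.12 (SE 0.16), or 4.35-fold. Scd, the stearoyl-CoA desaturase, fell 7.63-fold and the pheromone carrier Obp3 fell 32.5-fold by its brighter probe set and 4.16-fold by the other, whereas Sds, the serine dehydratase that feeds serine into glucose synthesis, rose 4.25-fold and Pla1a, a phosphatidylserine phospholipase, rose 3.72-fold. The sufficient level of Pla1a, 6.18 ± 0.23, lay under the filter at 6.196, so the size of its rise is uncertain: it was 2.17 on the log2 scale with a pseudocount of 1 and 1.38 with 64.

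Over all 5244 probe sets tested, 90 passed an adjusted p of 0.05 in limma, 39 higher and 51 lower in deficient livers, and 759 had an unadjusted p under 0.05. Taken as 3135 genes with 1 probe set each, 26 rose and 33 fell. With every array set to a common median, 77 probe sets passed, 17 higher and 60 lower, and the calls of Arg1, Abcb4, Vim, Cd63, Ifitm3, Lgals3, RT1-Ba, RT1-Bb, RT1-Da and RT1-Db1 were lost, at adjusted p between 0.0644 and 0.153, although their differences, now 0.57 to 0.96, stayed about as large as the 0.63 to 1.03 found before. The count was 58 without sufficient animal 3, 49 without deficient animal 4, and 250 with the 14 arrays fitted one by one and diet and number as a random block. Neither measure of RNA quality differed between the diets beyond the spread: the log2 ratio of 3' to 5' signal differed by 0.0625 for GAPDH (exact two-sided permutation p = 0.743) and by -0.095 for beta-actin (exact p = 0.457). Markers of erythroid cells did move with the diet, and 1 of 9 macrophage markers passed, as given with the gene groups.

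**Figure D1:**
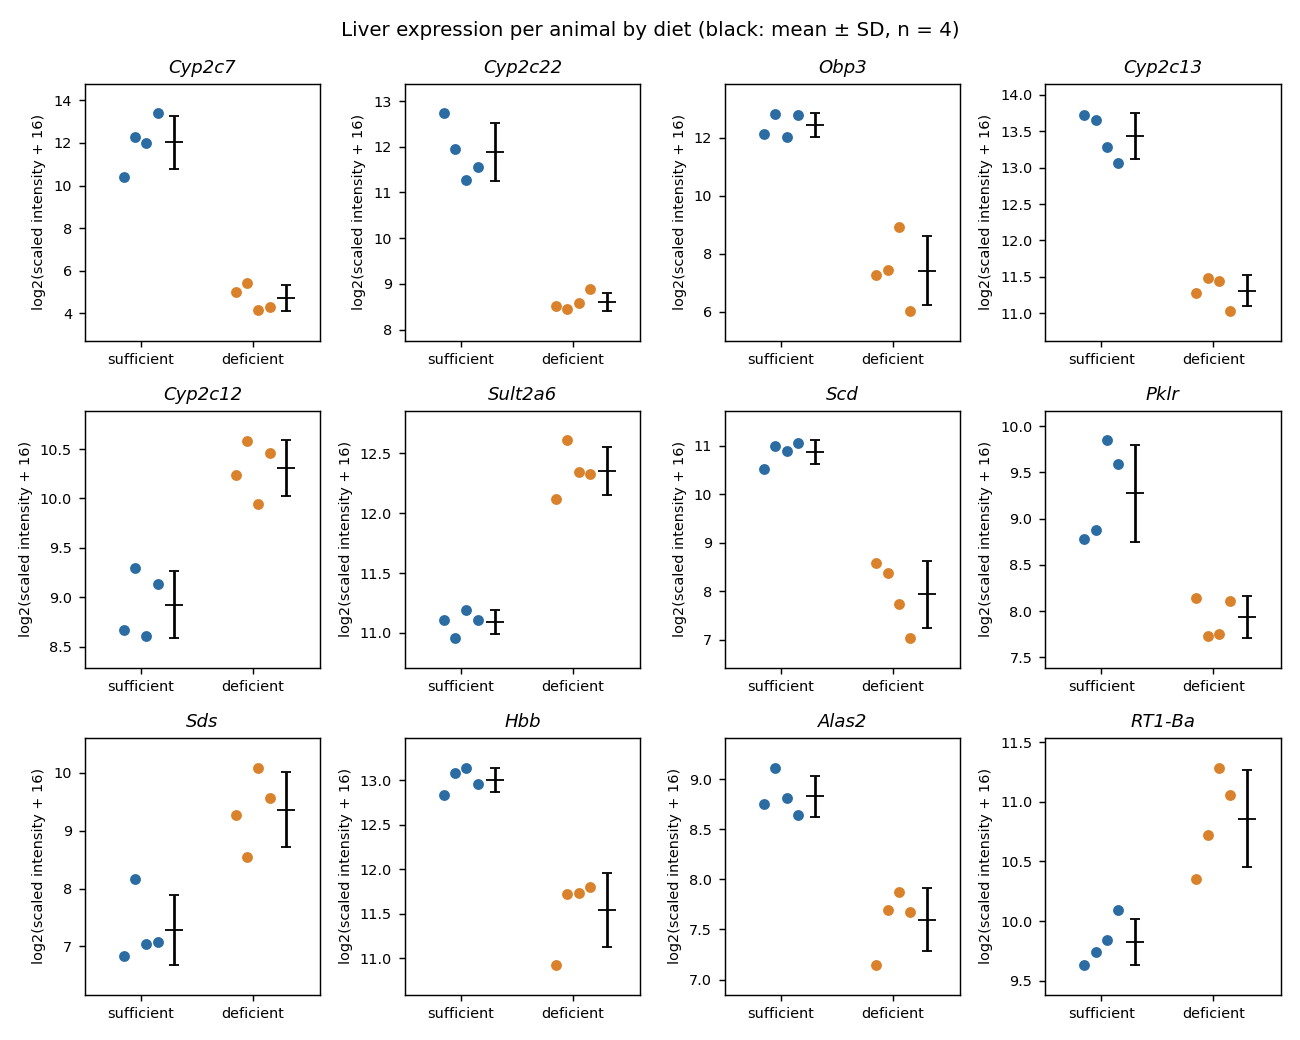
Level of 12 genes in each animal, as log2 of the scaled intensity plus 16 on the vertical axis, with sufficient animals in blue, deficient animals in orange and black bars for the mean ± SD of 4 animals. Cyp2c7 lay between 10.40 and 13.40 in the sufficient animals and between 4.14 and 5.41 in the deficient animals, and the 2 diets do not overlap in any of the 12 genes. These genes were picked from those that passed on the same values, so the lack of overlap follows in large part from the selection.

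Cyp2c7 was the 1 gene to pass the test among the 14 tested members of the list on retinoid handling and the retinoic acid response, both over all probe sets and adjusted over the list alone. Its deficient level lay close to 4, the value of an intensity of 0 on this scale, so the size of the fall depended on the pseudocount: it was -8.91 with a pseudocount of 1 and -5.82 with 64. In 3 further probe sets that passed, annotated to both Cyp2c7 and Cyp2c7l1, the differences were smaller, at -5.45, -4.76 and -4.67. The level of Rbp4, the plasma retinol carrier, was 14.74 ± 0.07 in deficient and 14.61 ± 0.05 in sufficient livers (difference 0.13, SE 0.08, adjusted p = 0.501), and that of Aldh1a1, a retinal dehydrogenase, was 12.42 ± 0.28 against 11.94 ± 0.65 (adjusted p = 0.484). Rarb, a retinoic acid receptor, and Crabp1, a retinoic acid-binding protein, were too dim to be tested, with means of 5.83 ± 0.42 against 6.34 ± 1.01 and 5.73 ± 0.48 against 5.42 ± 0.36 in deficient and sufficient livers. Lrat, Cyp26a1 and Tgm2 were not analysed here. The list as a whole was not called by camera (adjusted p = 0.648), and its median of 0.08 and mean of -0.49 differed in sign, the test pointing down.

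Genes that differ between the sexes in rat liver moved in both directions. Of 11 tested male-predominant genes, 3 fell: Obp3, from 12.43 ± 0.42 to 7.41 ± 1.18, Cyp2c13, and the sulfotransferase Sult1c3, which fell 2.36-fold (log2 difference -1.24, SE 0.16). Adjusted over the list alone, 5 fell, adding Cyp2c11 at -0.30 (SE 0.11) and the carbonic anhydrase Car3 at -1.16 (SE 0.29). The list was called lower by camera (adjusted p = 5.1e-06) but not with an estimated correlation (adjusted p = 0.230 with an estimated correlation), and its median of -0.09 was small against its mean of -0.88. Of 7 female-predominant genes, Cyp2c12 rose 2.60-fold (log2 difference 1.38, SE 0.19), the bile acid sulfotransferase Sult2a6 rose 2.40-fold (1.26, SE 0.12), Cyp2c7 fell, and 4 did not pass. The Cyp2c12 call was 1 of 21 calls of named genes lost in the 2 µg arrays alone (1.25, limma adjusted p = 0.103). With the clock gene Dbp as a covariate, chosen after seeing the data, the calls of Cyp2c12 (1.16, adjusted p = 0.205) and Sult1c3 (-1.32, adjusted p = 0.0664) were lost, at differences about as large. Adjusted over the list alone, 5 rose and 1 fell. Camera called the female-predominant list higher (adjusted p = 0.0101), with a median of 0.83 but a mean of -0.32 because of Cyp2c7, and the call was lost with an estimated correlation (adjusted p = 0.380 with an estimated correlation). Probe sets of the Cyp2c and Sult2a families and of Obp3 can bind transcripts of near relatives, so the gene behind each of these values is uncertain.

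In the growth hormone and IGF list, Ghr, the growth hormone receptor, fell 2.31-fold (log2 difference -1.21, SE 0.19), although only 1 of its 3 probe sets passed. With Dbp as a covariate the Ghr call was lost, at -1.31 (limma adjusted p = 0.176). The other 20 members did not pass; adjusted over the list alone, 2 fell, Ghr and the deiodinase Dio1 (-0.70, SE 0.16). Camera did not call the list (adjusted p = 0.0589), with a median of 0.02, a mean of -0.11 and a test pointing down, whereas fry called it lower (adjusted p = 0.0460).

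Of 19 tested enzymes and regulators of fatty acid and triglyceride synthesis, 3 fell and 16 did not pass. Scd fell from 10.87 ± 0.24 to 7.93 ± 0.70, the pyruvate kinase Pklr fell 2.53-fold (log2 difference -1.34, SE 0.23), and the transketolase Tkt fell 1.75-fold (-0.81, SE 0.15). Only 1 of the 2 Tkt probe sets passed, the other giving -0.72. Adjusted over the list alone 6 fell, adding Acly, Me1 and Elovl5, and 16 of the 19 differences were negative. The Tkt call was lost without sufficient animal 3 or without deficient animal 2, 3 or 4, at an adjusted p of up to 0.0602. Fasn, the fatty acid synthase, was -0.40 (SE 0.19) by its brightest probe set, which did not pass, and -0.99 (SE 0.21, adjusted p = 0.0417) by another. Camera called the list lower (adjusted p = 2.0e-07), but not with an estimated correlation (adjusted p = 0.110 with an estimated correlation). Among 30 genes of fatty acid oxidation, the peroxisomal thiolase Acaa1b fell 2.23-fold (-1.16, SE 0.15) and 29 did not pass. Adjusted over that list alone 1 fell and 1 rose, the fatty acid transporter Slc27a2 (0.38, SE 0.08), and the list was not called (adjusted p = 0.335).

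Of 35 tested enzymes of amino acid breakdown and the urea cycle, 3 rose: Sds, from 7.28 ± 0.61 to 9.37 ± 0.65, the tryptophan dioxygenase Tdo2, which rose 1.88-fold (log2 difference 0.91, SE 0.14), and the arginase Arg1, which rose 1.55-fold (0.63, SE 0.13). Oat, the ornithine aminotransferase, fell 2.16-fold (-1.11, SE 0.20) by 1 of its 2 probe sets, the other giving -0.89 without passing. The remaining 31 genes did not pass. Adjusted over the list alone 9 rose and 2 fell, and 27 of the 35 differences were positive. The Arg1 call held in only 1 of the 8 fits that left out 1 animal, that without sufficient animal 2, with an adjusted p of up to 0.0956 in the others, and the Oat call was lost without sufficient animal 3 or deficient animal 4, at up to 0.0660. With the clock gene Dbp as a covariate, chosen after seeing the data, the Sds difference was 1.20 (SE 0.40, adjusted p = 0.393) and the calls of Tdo2, Arg1 and Oat were lost too. Of these, Tdo2 changed little in size, at 0.85 (SE 0.23), while Arg1 was 0.45 (SE 0.19) and Oat -0.80. Camera called the list higher (adjusted p = 0.00506), but not with an estimated correlation (adjusted p = 0.181 with an estimated correlation). In the glucose metabolism list, which shares Sds and Pklr, 1 rose, 1 fell and 18 did not pass, 1 rose and 2 fell adjusted over the list alone, and the list was not called (adjusted p = 0.0589).

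Erythroid transcripts were lower in deficient livers. Of 6 tested markers of erythroid cells, 4 fell: the beta globins Hbb, from 13.01 ± 0.14 to 11.54 ± 0.42, and Hbb-b1 (log2 difference -1.32, SE 0.17), the alpha globin Hba-a3 (-0.98, SE 0.14), and Alas2, the erythroid enzyme that begins heme synthesis (-1.23, SE 0.17). The same 4 fell adjusted over the list alone. The remaining members were Slc4a1 at -0.13 (SE 0.12) and Tfrc at -0.37 (SE 0.25). The list was called lower by camera (adjusted p = 3.4e-09) and, alone among the lists, with an estimated correlation too (adjusted p = 0.0456 with an estimated correlation). Globin probe sets can share targets, so they do not count as separate genes with certainty.

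In the list on interferon and antigen presentation, 4 of 23 tested members rose, all of them MHC class II chains, a grouping made after their values were seen: RT1-Ba rose 2.04-fold (log2 difference 1.03, SE 0.19), RT1-Db1 1.95-fold (0.96, SE 0.21), RT1-Bb 1.90-fold (0.92, SE 0.16) and RT1-Da 1.84-fold (0.88, SE 0.17). Adjusted over the list alone 7 rose, adding Cd74, RT1-DMa and RT1-DMb, which also serve class II presentation but did not pass over all probe sets. With every array set to a common median none of the 4 class II chains passed, at differences of 0.81 to 0.96 that were about as large. The other tested probe sets of RT1-Ba, RT1-Bb, RT1-Da and RT1-Db1 were higher too, by 0.23 to 1.06, but none of them passed. The RT1-Ba, RT1-Da and RT1-Db1 calls each failed in some fits that left out 1 animal, among them those without sufficient animal 2 or 3 or deficient animal 4, at adjusted p of up to 0.0825, 0.0698 and 0.149. Camera called the list higher only just (adjusted p = 0.0468; adjusted p = 0.560 with an estimated correlation), and without deficient animal 3 its median was -0.03 (adjusted p = 0.329). The call was also lost without sufficient animal 2 or 3, with arrays set to a common median (adjusted p = 0.0700) and with diet and number as a random block (adjusted p = 0.129).

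Of 9 tested macrophage markers, Lgals3, a galectin, rose 1.71-fold (log2 difference 0.77, SE 0.17) and 8 did not pass; adjusted over the list alone 2 rose, Lgals3 and the cathepsin Ctss (0.65, SE 0.16). The Lgals3 adjusted p of 0.0492 rose over the threshold, to at most 0.133, in each of the 8 fits that left out 1 animal. The macrophage list was called higher by camera (adjusted p = 0.0151; adjusted p = 0.551 with an estimated correlation), with a median of 0.27. It was not called by fry (adjusted p = 0.117), in the 2 µg arrays alone (adjusted p = 0.188) or without deficient animal 3 (adjusted p = 0.114). In the acute phase list none of 29 genes passed in limma, over all probe sets or adjusted over the list alone, and 24 of the 29 differences were positive. That list was called higher (adjusted p = 0.0101; adjusted p = 0.551 with an estimated correlation), with a median of 0.16, but not without sufficient animal 3 or deficient animal 3 (adjusted p of up to 0.144).

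Vim, a filament protein of stellate and other mesenchymal cells, rose 1.74-fold (log2 difference 0.80, SE 0.16) as the 1 of 19 stellate cell and matrix genes to pass. Its call was kept only without deficient animal 1 or deficient animal 3 (adjusted p of up to 0.108 in the others). Lyve1, a receptor of sinusoidal and lymphatic endothelium, fell 2.06-fold (-1.04, SE 0.16) as the 1 of 8 endothelial genes to pass. Abcb4, the phospholipid transporter of the bile canaliculus, rose 1.74-fold (0.80, SE 0.17) as the 1 of 20 bile acid genes to pass, and kept its call only without sufficient animal 1 or deficient animal 2 (adjusted p of up to 0.126 in the others). Adjusted over each list alone, the stellate list had 1 gene higher and 1 lower, the endothelial list 0 and 1, and the bile acid list 2 and 2. The 3 lists were not called, at adjusted p of 0.707, 0.308 and 0.790.

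Among the other genes with large changes, Avpr1a, a vasopressin receptor, fell 2.50-fold (log2 difference -1.32, SE 0.13), from 10.06 ± 0.18 to 8.74 ± 0.10. The acyl-CoA synthetase Acsm3 fell 3.22-fold (-1.69, SE 0.27) and the lipoxygenase Alox15 fell 3.13-fold (-1.65, SE 0.32), while the probe set annotated to Rpp21 fell 3.22-fold (-1.69, SE 0.15). Eef2k, a kinase of translation elongation, rose 2.14-fold by 1 of its 2 probe sets (1.09, SE 0.16), the other giving 0.15. The membrane proteins Cd63, Ifitm3 and Myadm rose 2.03-fold, 2.01-fold and 1.89-fold, and the calcium-binding family member S100a10 rose 1.91-fold. The Alox15 call was lost without sufficient animal 2 or 3 or deficient animal 2 or 4 (adjusted p of up to 0.0883), and the Cd63 call without sufficient animal 2 or deficient animal 2, 3 or 4 (up to 0.0668). Ifitm3 kept its call only without sufficient animal 4 or deficient animal 2 (up to 0.0848 in the others), and S100a10 only without sufficient animal 1 or 4 or deficient animal 2 (up to 0.0901).

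Over the 28 gene lists with at least 5 tested genes, camera called 10, of which 5 were higher and 5 lower in deficient livers. Besides those described, ribosomal protein genes were called lower with a median of -0.05 (adjusted p = 0.0141; adjusted p = 0.551 with an estimated correlation), and genes of endoplasmic reticulum stress and heat shock with a median of -0.08 (adjusted p = 0.0101; adjusted p = 0.434 with an estimated correlation). In limma none of the 39 ribosomal or 21 stress genes passed, over all probe sets or adjusted over the list alone. The ribosomal call was lost without sufficient animal 4 (adjusted p = 0.350), and the stress call without sufficient animal 4 or deficient animal 1 (adjusted p of up to 0.113). With quantile normalization the calls of the ribosomal, stress, acute phase and interferon lists were lost, at adjusted p between 0.0519 and 0.0554.

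Most other lists held no gene that passed and were not called. These were cholesterol synthesis (median -0.18, adjusted p = 0.0784), lipoprotein metabolism (0.16, 0.0601), xenobiotic metabolism (-0.02, 0.0589), antioxidant and metal response (-0.03, 0.416), cell cycle (0.04, 0.604) and the respiratory chain (0.05, 0.790). For cell cycle and the respiratory chain the test pointed down while the median was positive, and so was the respiratory chain mean of 0.01. Adjusted over the list alone, xenobiotic metabolism had 3 genes higher and 6 lower, among them Cyp1a1 at 1.63 (SE 0.42) and Cyp2b2 at -2.05 (SE 0.60), and the others had none. The iron and heme list held 1 gene that fell, Alas2, and was not called (-0.03, 0.286). Markers of lymphocytes and NK cells (0.01, 0.790), bile duct cells (0.24, 0.347), pancreatic acinar cells (-0.11, 0.297) and muscle and adipose tissue (-0.15, 0.347) were not called. The lymphocyte median was positive while its test pointed down. In the bile duct list 1 gene was higher and 1 lower adjusted over the list alone, Spp1 and the water channel Aqp1 (-1.04, SE 0.24). Of the neutrophil markers only Lcn2 was bright enough to test (0.86, SE 0.38), and that list was not tested.

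**Figure D2:**
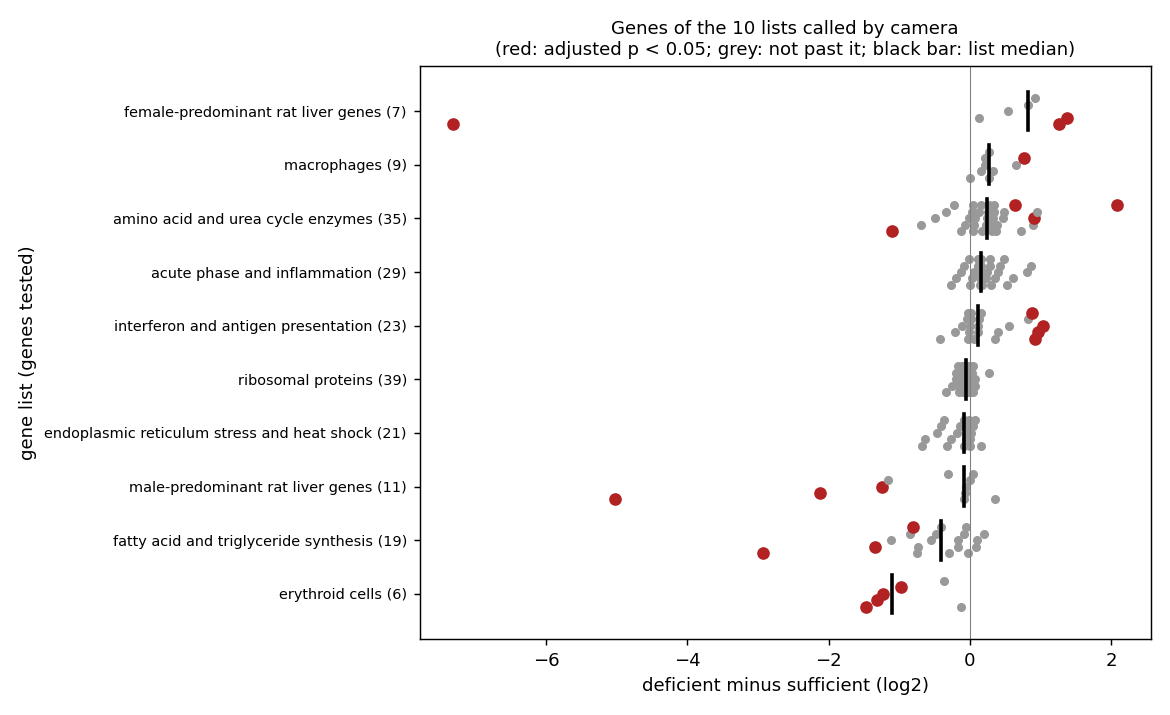
Difference between deficient and sufficient livers on the log2 scale (horizontal axis) for each tested gene of the 10 lists called by camera (vertical axis, genes tested in parentheses), with genes past an adjusted p of 0.05 in red and the list median as a black bar. In the erythroid list 4 of 6 genes are red and lie at or below -0.98, while in the ribosomal list all 39 genes are grey.

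The comparison of about 2 µg with about 10 µg of starting RNA asked how the amount changed the measured values. No gene passed the test: limma called 0 of 5244 probe sets, with 347 at an unadjusted p under 0.05 and a lowest adjusted p of 0.147. With each diet and number as a block, over 6 pairs, 2 probe sets passed. Ptms, or parathymosin, was lower in the 2 µg arrays by a log2 difference of -1.36 (SE 0.13, limma adjusted p = 0.00252). A probe set without a single gene symbol was higher by 0.84 (SE 0.10, limma adjusted p = 0.00644). In that fit 632 probe sets had an unadjusted p under 0.05. In the fit with pairs the median size of the difference over all probe sets was 0.11 on the log2 scale, and its 99th percentile was 0.70. Without sufficient animal 1 the fit without a block called 2 probe sets, and without sufficient animal 3 it called 1.

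The remaining comparison asked whether the diet difference depended on the RNA amount. Cyp2c7 differed by -7.19 in the 10 µg arrays and by -7.31 in the 2 µg arrays, Scd by -2.90 in both, Obp3 by -5.07 and -5.60, and Sds by 1.95 in both. Others differed more between the array sets: Pla1a by 2.20 and 1.31, Alox15 by -1.65 and -1.22, and Vim by 0.99 and 0.46. The interaction of diet and amount passed for 0 of 5244 probe sets in limma, with 96 at an unadjusted p under 0.05 and a lowest adjusted p of 1.00, and for 0 with diet and number as a random block. All 90 probe sets called by diet had the same sign in both array sets, but they were called on the average of these sets, so equal signs follow in large part from the selection. Tested alone, the 10 µg arrays, with 4 per diet, called 71 probe sets and the 2 µg arrays, with 3 per diet, called 33, of which 30 were called in both; these sets are not independent, since arrays of the same diet and number resembled each other.

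**Figure D3:**
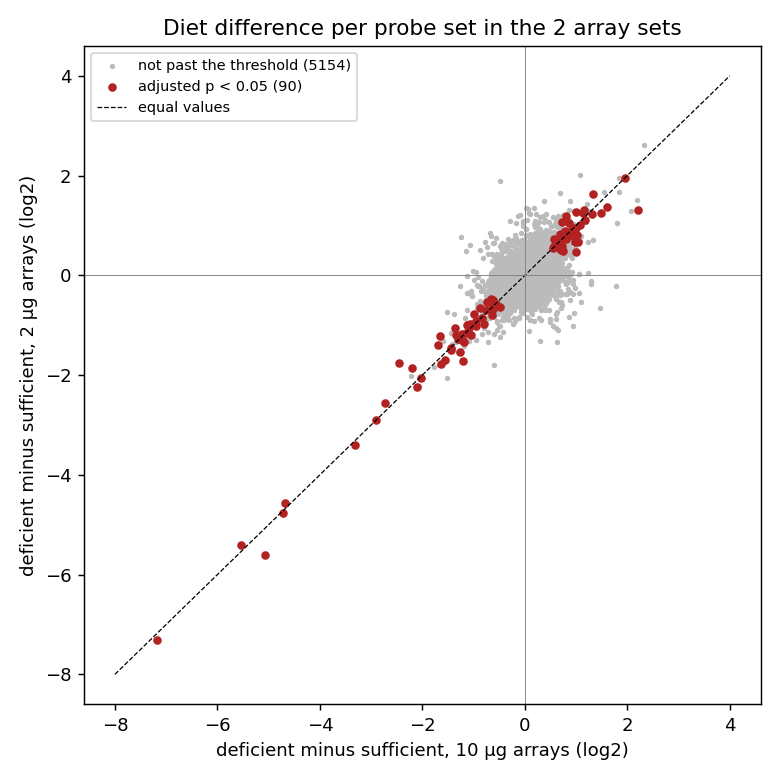
Deficient minus sufficient difference of each of the 5244 probe sets on the log2 scale in the 10 µg arrays (horizontal axis) against the 2 µg arrays (vertical axis), with the 90 probe sets past an adjusted p of 0.05 in red and equal values on the dashed line. The red points were called on the average of both array sets, and the lowest is Cyp2c7 at -7.19 and -7.31.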

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

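The tests of scaling, blood, time of day, food intake and cross-hybridisation, the splits for the RNA amount without a block and those for the interaction were chosen after the results they bear on were seen.

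Among 80 groups of 4 animals, a group being a named gene in 1 diet, 5 held an animal far from the other 3, and chance alone gives about 1 in 20. Hbb was 10.92 in deficient animal 1 against 11.73 to 11.80 in the others. Lgals3 was 10.03 in deficient animal 3, with the next at 9.48. That animal rests on a single array. Its log2 ratio of 3' to 5' signal was the highest of the 14 arrays for GAPDH, at 1.12, but not for beta-actin, at 0.486. The interferon, macrophage and acute phase lists lost their calls without it. Arg1 was 12.43 in deficient animal 4, with the next at 12.57. Acaa1b was 10.58 in sufficient animal 1, with the next at 10.09, and Ifitm3 was 11.69 in sufficient animal 4, with the next at 11.23.

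The real division of the 8 animals called 90 probe sets, and the highest of the other 34 called 1. Thus 1 of 35 splits reached the real count, which argues against chance as its origin but cannot exclude it. With 35 splits no smaller share is possible, and the other splits mix the diets, which raises the spread within their groups. For the number of called lists chance is not argued against. There 4 of 35 splits gave 10 lists or more, and the highest of the others also gave 10. Single lists differed in this respect: the erythroid, male-predominant and amino acid lists had their smallest camera p in 1 of 35 splits, the real one, and the lipid synthesis list was matched by 1 other split (2 of 35). The female-predominant list was as extreme in 3 of 35, the macrophage list in 7, the stress list in 8, the acute phase list in 12, the ribosomal list in 14 and the interferon list in 15. These shares were not adjusted for the 28 lists tested, so they cannot exclude chance for any single list.

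For the RNA amount and for the interaction the real division called 0, which all 100 drawn splits reach by construction, so these counts say nothing about chance. The highest of the other drawn splits called 12 for the RNA amount and 24 for the interaction. With the 6 pairs as a block, 2 of 32 splits that part every pair gave 2 probe sets or more, with a highest other of 2, so chance cannot be excluded there. Without the block, 6 of the 100 drawn splits called any probe set for the RNA amount, and 7 of the 64 splits that part every pair, as the real one does, with at most 2 probe sets. For the interaction the numbers were 10 of 100 and 4 of 64, again with at most 2 in the latter. Arrays of the same diet and number correlated at 0.202 to 0.351 in all 6 pairs, and splits that part every pair did not reach counts of 12 or 24. Whether the pairs caused those counts was not tested.

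The fall of erythroid transcripts was weighed against array scaling and against less blood left in the deficient livers. Under median scaling and quantile normalization the erythroid list median stayed at or below -1.16, against -1.11 in the diet comparison, which argues against scaling. Less blood stays open: the lymphocyte and NK cell list had a median of 0.0093, but lymphocytes resident in liver may set that level, and their share was not measured. A lower output of red cells, as a response to diet, was not tested.

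The lower mean of the lipid synthesis list, in which 3 of 19 genes passed, was weighed against the time of day of collection, read from the clock gene Dbp, and against lower food intake. The mean over the 19 list members was -0.54 (95% interval -0.87 to -0.21) and became -0.34 (-0.83 to 0.15) with Dbp as a covariate, so time of day cannot be told apart from diet for the list, because Dbp itself was uneven between the diets and the interval widened. The Scd difference did not shrink with Dbp in the limma fit, at -2.97 (SE 0.46, adjusted p = 0.0282) against -2.93 (SE 0.29) without it. Pklr was -1.40 (SE 0.37, adjusted p = 0.236) against -1.34 (SE 0.23) and Tkt -0.51 (SE 0.20) against -0.81 (SE 0.15). Both lost their calls as their errors widened, and Tkt also as its difference shrank. Dbp varied little among the deficient animals (9.09 to 9.63 by its brighter probe set), so its slope rests mainly on the 4 sufficient animals. The fit therefore cannot decide on time of day for single genes, Scd included. Lower food intake stays open, since the fatty acid oxidation list, at a median of -0.020, held genes moving both ways, such as Pdk4 at -1.10 (SE 0.49) and Cpt1a at 0.70 (SE 0.23), neither past the threshold. The diet itself stays open as well.

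The lower Cyp2c13 and Cyp2c22 signals were weighed against cross-hybridisation, that is, loss of Cyp2c7 transcripts that had bound to their probes. If that were so, the 3 probe sets would follow the log2 levels predicted from Cyp2c7 among the sufficient animals with a slope of 1. The slope of their mean on the mean predicted level was -0.33 (95% interval -0.97 to 0.32). Sufficient animal 4 exceeded animal 1 in Cyp2c7, at 13.40 against 10.40, and the mean of the 3 probe sets was lower there by a log2 difference of -0.80 where cross-hybridisation predicted 2.32. This argues against cross-hybridisation from Cyp2c7 as the whole of the fall, and other transcripts of the family were not tested. A response of these genes to the diet stays open, as untested.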

How the results depend on the processing

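Dbp as a covariate was chosen after seeing the data; the other settings were planned. Against the 90 probe sets called by diet, 349 were called with the 14 arrays as separate samples, 250 with diet and number as a random block, 33 in the 2 µg arrays alone and 21 with Dbp as a covariate; all 90 were among the 349 and the 250. The 2 µg arrays hold 3 samples per diet, and the covariate takes up a degree of freedom and is uneven between the diets. Of the 38 named genes that passed, 21 lost their call in the 2 µg arrays alone and 27 with Dbp. Both lost Acsm3, Alox15, Pklr, Oat, Lyve1, Tkt, Arg1, Lgals3, Abcb4, Vim, Tdo2, Myadm, S100a10, Ifitm3, Cd63, Cyp2c12, Pla1a and the called class II chains. Sult1c3, Ghr, Acaa1b, Hba-a3, Eef2k and Sds were lost with Dbp only. The fit that called 349 counts arrays of the same diet and number as independent, although they correlated at 0.202 to 0.351. Its p-values therefore do not measure the spread between animals, and 349 overstates the evidence. For the count of 250 the cause was not tested. Leaving out 1 animal gave 49 to 97. The remaining settings gave 66 to 110. For the RNA amount, the count of 0 became 2 with the replicate block of diet and number, 1 without number 3, and 0 to 2 leaving out 1 animal; the cause was not tested. The interaction gave 0 in every setting, including each animal left out. Of 10 lists, quantile normalization and the 2 µg arrays alone each called 6, an estimated correlation 1 and fry 5, 4 of them among the 10 and the other the growth hormone list; leaving out 1 animal gave 7 to 13. The cause was not tested. Numbers shared across the diets did not pair the animals: deviations of equal numbers correlated at -0.076 to 0.067. With the number as a replicate block the diet comparison called 77 probe sets, 63 of them among the 90, and 12 lists; diet and number as a block left the interaction at 0. Over all settings, named genes kept direction and side of the threshold in 764 cases and direction alone in 152, and called lists in 195 and 35. The direction of a list is that of its test; the median of the interferon list changed sign, to -0.03, without deficient animal 3. With no detection calls, signal over background limits dim genes such as Cyp2c7 in deficient livers.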

Other observations

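Apart from Avpr1a, the genes given here lie outside the rule for named genes and were picked after their values were seen. Agtr1a, an angiotensin II receptor, was 1.59-fold higher in deficient livers (log2 difference 0.67, SE 0.13, limma adjusted p = 0.0279), while the vasopressin receptor Avpr1a was lower. Serpina6, the corticosteroid-binding globulin of plasma, fell 1.79-fold (-0.84, SE 0.15), from 12.02 ± 0.21 to 11.19 ± 0.25. Alox5ap, which presents arachidonic acid to 5-lipoxygenase, rose 1.59-fold (0.67, SE 0.12) by 1 of 2 probe sets, lying between 8.03 and 8.17 in deficient and between 7.39 and 7.45 in sufficient animals. The alarmin Il33 rose 1.85-fold (0.89, SE 0.18) and the protease inhibitor Cst3 1.63-fold (0.70, SE 0.13), as did the lysosomal protease Ctsl, 1.48-fold (0.56, SE 0.10). Mif, a cytokine, fell (-0.59, SE 0.11). The other probe sets of Alox5ap (0.69), Cst3 (0.73), Ctsl (0.60) and Mif (-0.30) had the same sign but did not pass, and 2 of the 4 for Agtr1a passed.

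In lipid and carbohydrate handling, the acyl-CoA synthetase Acsl4 fell 1.56-fold (-0.65, SE 0.14), the phosphatidylcholine transfer protein Pctp fell 1.66-fold (-0.73, SE 0.16) and Tkfc, the triokinase of fructose metabolism, fell 2.19-fold (-1.13, SE 0.17). Plin2, the lipid droplet coat protein, fell 2.02-fold by 1 probe set (-1.01, SE 0.18) but was at -0.28 (SE 0.22) by the other. Ldhd, a lactate dehydrogenase of mitochondria, fell 1.52-fold (-0.60, SE 0.11).

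Dbp, a transcription factor with a strong daily rhythm in liver, had the widest spread among the genes looked at: 4.60, 9.28, 7.59 and 6.49 in sufficient animals 1 to 4, against 9.09 to 9.63 in the deficient animals (difference 2.36, SE 0.74, adjusted p = 0.160). Other clock genes looked at differed less, and none passed. Per2 was at 0.03 (SE 0.29), Bhlhe40 at -0.005 (SE 0.15), Tef at 0.24 (SE 0.14), Nr1d1 at 0.86 (SE 0.27) and Nr1d2 at 0.75 (SE 0.28). Like Dbp, Nr1d1 and Nr1d2 were lowest in sufficient animals 1 and 4. Nr1d1 was 7.18, 8.11, 7.95 and 6.75 in sufficient animals 1 to 4, against 8.12 to 8.63 in the deficient animals. Nr1d2 was 6.64, 7.74, 7.72 and 6.71, against 7.55 to 8.24. Per2, Bhlhe40 and Tef instead had their highest sufficient value in animal 4. Only Dbp was used to read the time of day. Cyp2b2, a P450 inducible by drugs, was 12.05 to 13.22 in the sufficient animals and 9.06, 12.38, 11.71 and 10.05 in deficient animals 1 to 4 (difference -2.05, SE 0.60, adjusted p = 0.134).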
